A study of Drosophila melanogaster with 3 samples.

How the data were processed

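The data were chromatin immunoprecipitation sequencing (ChIP-seq) of the fruit fly Drosophila melanogaster. Per the labels, the embryos came from a transgenic line that stably carried Deadpan (Dpn) with a green fluorescent protein (GFP) tag at its C-terminus, and the precipitation used an antibody to GFP. Dpn is a basic helix-loop-helix repressor of the Hairy and Enhancer of split class that is known from neural stem cells (neuroblasts). Per the labels, whole embryos of both sexes from 0 to 16 h of development were pooled, chromatin was sonicated, and fragments of 200 to 800 bp were used. There were 3 biological replicates of 1 group and no comparison group, so no difference between groups was tested.

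The deposited files were peak lists on the genome builds dm6 and dm3. For each build there was 1 list per replicate, 1 relaxed list called on the pooled replicates, and 1 thresholded list. Per the deposited text listings of the files, the relaxed lists were meant as input for the irreproducible discovery rate (IDR) procedure and hold background by design, and a control file entered each call. The same listings name the 3 replicate lists and the pooled list as the source of the thresholded dm6 set, and the replicate 2 list and the pooled list as the source of the dm3 set. The aligner, the peak caller, the IDR limit and the read depth were not given in the sources used here, and no peak list of a control library was analysed here. The signal of each peak is the authors' value, as deposited, in an undefined scale, and was used here to rank peaks within a list. The −log10 of the q-value is also as deposited by the authors, and all 6253 peaks of the dm6 thresholded set shared its single top value, so it could not grade them. The summit position was taken as deposited, as an offset from the start of the peak. All 6253 thresholded peaks were peaks of the pooled list, and they were its first 6253 by signal.

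The reference was Release 6 of the genome, which is the dm6 build, with gene models of Ensembl release 115 (BDGP 6.54). Only the arms 2L, 2R, 3L, 3R, 4 and X were used, transposable elements were left out of the gene models, and 13945 protein-coding genes remained. Peaks on dm3 were counted and overlapped with each other, and they were not annotated or converted. Coordinates below are 1-based on dm6.

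The tests, the gene lists and the alternatives were fixed before the data were examined. Replicates were compared by the share of each one's first 6253 peaks that overlapped a first-6253 peak of another by at least 1 bp, with 100 shuffles of one list within arms as the chance level. Each summit was put in 1 of 7 classes in the order promoter (within 500 bp of an annotated start site), 5′ untranslated region (UTR), coding sequence (CDS), 3′ UTR, intron, non-coding exon and intergenic. Shares were set against 100000 circular rotations of all summits within arms, with a two-sided permutation p adjusted by Benjamini-Hochberg over the classes. DNA words were counted on either strand within 50 bp of the summit and in a window of the same width 500 bp away, on the left for one peak and on the right for the next, and compared with a two-sided exact McNemar test adjusted over 13 words. The relation of signal and site was a two-sided permutation test (100000 permutations) of Spearman's rho across peaks, which are not independent replicates. A protein-coding gene was called bound when its start site was the nearest to at least 1 thresholded summit. Gene lists were tested with a two-sided exact test of the bound count within 10 strata of the length of sequence nearest to each gene, adjusted over 22 lists. Of the listed symbols, E(spl)m1, BobB and Nrarp were not matched to a protein-coding gene of the annotation, and h, Dl, wee and nct were matched under their current symbols hry, Delta, Wee1 and Nct. Genes named below are dpn, the 20 genes nearest to the strongest peaks, and up to 4 members per list with the strongest peaks, with all unbound members of the Hairy/Deadpan, proneural, pair-rule and gap lists. Intervals of shares are exact 95% binomial intervals. Those of folds and log2 ratios are 95% intervals from a normal approximation on the log scale, except where a bootstrap is named. All cover counting error only.

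The tests were checked on simulated data. With lists of 15 genes that had no effect, drawn toward long neighbourhoods among the 13945 genes, the stratified test gave p below 0.05 in 3.2% of lists, against 19.6% without strata, and it found 91.8% of lists whose members were bound with probability 0.9. No lower probability was simulated, so the power to find weaker excesses is not known. Lack of a call for a gene list therefore does not show lack of an excess. CACGTG planted in 20.1% of 6253 windows at random positions brought its share from 1.07% to 20.9%, and a set with a planted promoter share of 39.3% was read as 39.7%. The planted windows were set against the same windows before planting, which checks the matching of words only. The comparison with flanks called no word at random positions. It was not tried on a planted excess or on windows that differ from their flanks in GC as the summits do. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

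The alternatives were the dm3 lists, the 3126 peaks of highest signal, leaving out each replicate in turn, other overlap rules, a wider promoter, coding transcripts alone, the peak midpoint, other window widths and control sequences for the words, and other rules and backgrounds for bound genes. One alternative, the peaks found in all 3 replicates, was added after the data had been seen. Leaving out a replicate meant taking the first-6253 peaks of one remaining replicate that overlapped those of the other.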

Results

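Binding of GFP-tagged Dpn was measured in whole fly embryos of 0 to 16 h, in 3 biological replicates of 1 group. The question the design addresses is where in the genome Dpn sits in the embryo, and how far the replicates agree on it. The authors' thresholded set held 6253 peaks on dm6, with a median width of 420 bp and a signal from 122.4 to 4420.7. The relaxed lists held 30000 peaks for replicate 1, 22475 for replicate 2, 30000 for replicate 3 and 30000 for the pooled replicates. The thresholded dm3 set held 5918 peaks.

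Peaks spread over the large arms in near proportion to their length. Arm 2L held 1164 peaks, 2R 1100, 3L 1303, 3R 1487 and X 1176. The X chromosome took 18.8% of peaks (95% interval 17.8 to 19.8) and makes up 17.6% of the sequence. The small chromosome 4 held 23 peaks, or 0.368% (0.233 to 0.551) of peaks on 1.01% of the sequence.

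The dpn gene itself (FBgn0010109, 2R, 8228971 to 8232330) had no thresholded peak. The nearest thresholded summit lay 5078 bp from a dpn start site, at 8237408, and was nearer to the start of another gene. In the relaxed pooled list the nearest summit lay 1301 bp away and ranked 26741 of 30000. The relaxed list of replicate 3 had a summit 327 bp from the start at rank 4649, that of replicate 2 a summit 353 bp away at rank 19162, and that of replicate 1 a summit 1308 bp away at rank 24020. None of these passed the authors' threshold.

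The strongest peaks lay mostly at promoters. The first, at 3L from 19590397 to 19590855 (signal 4420.7), had its summit 101 bp from the start of CG14100. The next, on X from 2703665 to 2704118 (signal 4413.77), lay 42 bp from the start of Ugalt, which encodes a transporter of UDP-galactose. A peak at 2L from 480827 to 481346 (3748.7) lay in an annotated intron, with the start of cbt, a zinc-finger transcription factor gene, nearest at 1376 bp. The fourth, at 3R from 16280499 to 16280958 (3709.99), lay 157 bp from the start of the kinase gene gish. Of the 20 genes nearest to the strongest peaks, 14 had a promoter summit. Besides CG14100, Ugalt and gish these were px, Chro (a chromodomain protein gene, signal 2830.89), CenG1A, CG1888, mRpL41 (a mitochondrial ribosomal protein gene, 2597.87), PNPase, ph-p (a Polycomb group gene, 2491.98), Art3, larp, CG8320 and CHMP2B. The summits at cbt, CG11050, Lk6 and CG32772 were intronic, and those nearest to CG13323 (11908 bp away) and tara (3170 bp away) were intergenic.

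The replicates shared most of their strongest peaks. Among the first 6253 peaks of each, replicates 1 and 2 shared 72.9%, replicates 1 and 3 shared 78.8%, and replicates 2 and 3 shared 82.1%, a mean of 77.9% ± 4.7 (SD over 3 pairs). Shuffled lists, with peaks placed anywhere on their arm, shared 3.49%, 3.47% and 3.36% on average. This level does not account for a preference for promoters that all lists may share. Across the shared peaks, the signal had a Spearman rho of 0.71, 0.75 and 0.82 for the same pairs, which describes peaks and not independent samples. With all peaks of the relaxed lists the mean share was 61.3%.

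Of the 6253 thresholded peaks, 81.3% overlapped a first-6253 peak of replicate 1, 86.0% one of replicate 2 and 92.3% one of replicate 3. All 3 replicates held 4259 of them (68.1%), and 24 were held by none. The set came from a call on the same replicates pooled, so this support is not an independent check of it. Support depended on signal. In the strongest quintile, 99.8% of peaks were found in all 3 replicates, and the share was 97.4%, 83.8%, 47.0% and 12.5% in the following quintiles. A fall toward weak peaks is built into this measure. The set held the first 6253 pooled peaks, and each replicate was cut at the same rank, so the weakest quintile lay at the limit. With 2 times as many peaks of each replicate, support in all 3 was 93.2% over the whole set. The low share therefore does not show that weak peaks were absent from a replicate.

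**Figure D1:**
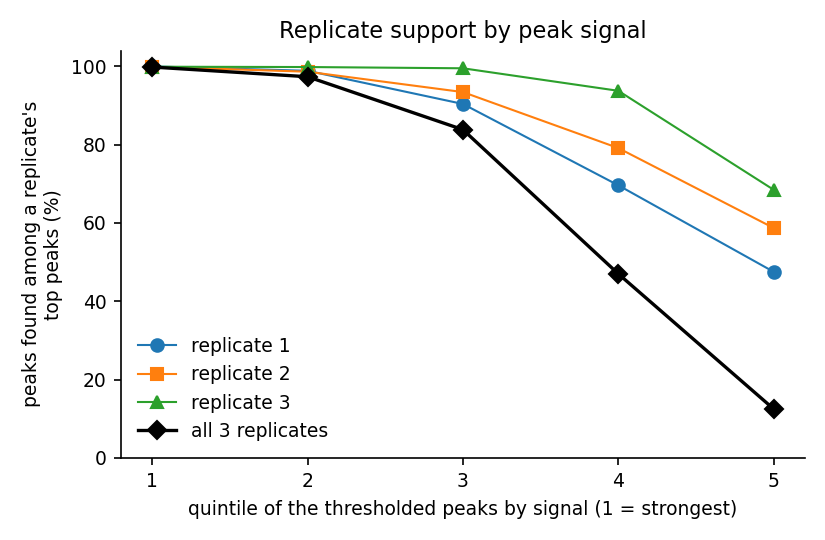
Share of thresholded peaks (vertical axis, percent) that overlapped a first-6253 peak of each replicate, by quintile of peak signal from strongest to weakest (horizontal axis). The black line, for peaks found in all 3 replicates, goes from 99.8% in the strongest quintile to 12.5% in the weakest. A fall toward weak peaks is built in, since the thresholded set and each replicate list were cut at the same rank.

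Promoters held the largest share of summits, and protein-coding sequence almost none. A start site lay within 500 bp of 3250 summits, or 52.0% (95% interval 50.7 to 53.2), where rotated summits gave 13.6%, a 3.83-fold difference. Introns held 2066 summits (33.0% against 39.7% by rotation, 0.83-fold) and intergenic sequence 815 (13.0% against 27.2%, 0.48-fold). Coding sequence held 14 summits (0.224%) against 13.7% by rotation. The 3′ UTRs held 0.736% against 4.43%. For each of these 5 classes the permutation p was 1e-05, the smallest that 100000 rotations can give (adjusted p = 1.4e-05). The 5′ UTRs outside promoters held 0.448% against 0.781% (permutation test, adjusted p = 0.0065), and non-coding exons 0.544% against 0.56% (adjusted p = 0.88). The median distance from a summit to the nearest protein-coding start was 522 bp, and 9.04% of summits lay over 10 kb away.

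**Figure D2:**
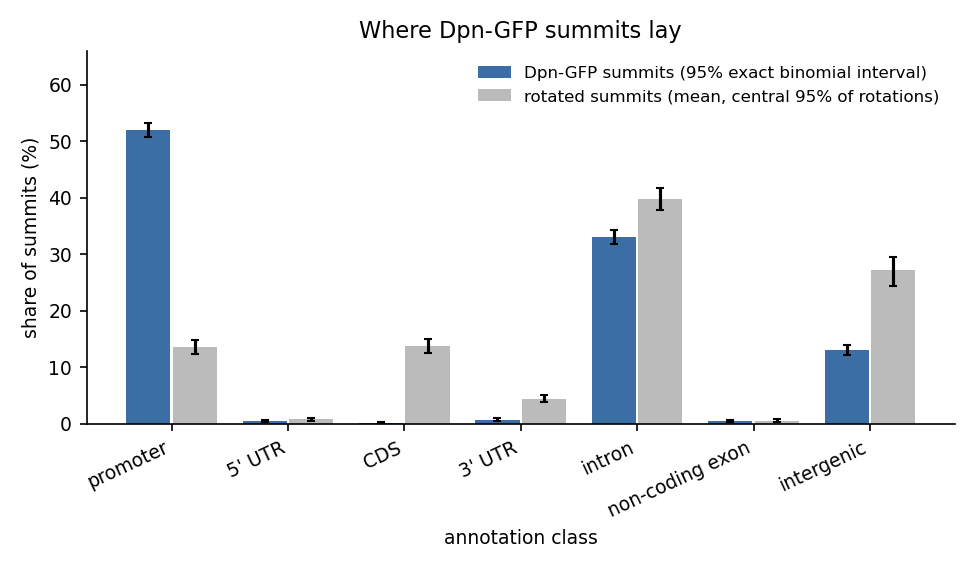
Share of summits (vertical axis, percent) in each annotation class (horizontal axis) for the thresholded set, with exact 95% binomial intervals, beside the mean of rotated summits with the central 95% of rotations. Promoters took 52.0% of summits against 13.6% by rotation, and coding sequence 0.224% against 13.7%.

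The E-box forms CACGTG and CACGCG, which proteins of the Hairy and Enhancer of split class are known to bind, were rare at the summits. CACGTG lay within 50 bp of 0.802% of 6235 summits and in 1.4% of flanking windows (log2 ratio −0.79, exact McNemar test, adjusted p = 0.0034). The call was lost without replicate 3, with the strongest peaks, with wider windows and with farther flanks (exact test, adjusted p = 0.071, 0.088, 0.053 and 0.2). The difference was called away from promoters (16 summits and 42 flanks, log2 ratio −1.37, exact test, adjusted p = 0.0018) and not at promoters (34 and 40, log2 ratio −0.23, adjusted p = 0.73). CACGCG was at 1.15% of summits and 3.05% of flanks (log2 ratio −1.39, exact test, adjusted p = 3.1e-13), and the wider form CACGNG at 4.33% and 8.74% (log2 ratio −1.01, adjusted p = 4.8e-23). CACGCG was called lower both at promoters (log2 ratio −1.30, exact test, adjusted p = 6.1e-08) and away from them (−1.37, adjusted p = 0.00014). So was CACGNG (log2 ratio −0.91 and −1.05). No test compared promoter summits with the others. The windows at summits were richer in A and T, with 34.6% GC against 44.2% and 43.9% at 500 bp on either side. Against shuffles of the same dinucleotides, the CACGTG and CACGCG differences did not pass the test (log2 ratio −0.48 and −0.42), while that of CACGNG did (−0.31, exact test, adjusted p = 0.013). Against low-ranked peaks matched on GC the log2 ratio was −0.29, −0.02 and 0.03 for CACGTG, CACGCG and CACGNG. No comparison with a control sequence gave a called excess of any of these 3 sites at summits. The N-box CACNAG, described below, was called in excess over low-ranked peaks matched on GC (10.9% and 9.21%, exact Fisher test, adjusted p = 0.013). It was called lower than in flanks, and its difference from shuffles did not pass the test.

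Either CACGTG or CACGCG was present at 123 of 6253 summits (1.97%, 95% interval 1.64 to 2.34). The share was 2.52% (2.01 to 3.12) of promoter summits and 1.37% (0.981 to 1.85) of the others. Only these E-box forms are called Dpn sites below. None of the 100 strongest peaks had one, which allows a share of up to 3.62%. By quintile of the signal, from strongest to weakest, the share was 1.2%, 2.08%, 2.48%, 1.92% and 2.16%. Across peaks, signal and the presence of a site had a Spearman rho of −0.014 (permutation p = 0.28).

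One fixed word was far more frequent at summits than beside them. TATCGATA, a word bound by the promoter factor Dref and not shown here to be particular to it, lay at 2.47% of summits and 0.289% of flanks (8.56-fold, exact McNemar test, adjusted p = 5.3e-27). The excess was at promoters, where 4.53% of summits and 0.247% of flanks had it (18.4-fold, exact test, adjusted p = 4.1e-33). Away from promoters it was present at 6 summits and 4 flanks (exact test, adjusted p = 0.89). GAGAG, the core of the GAGA factor site, lay at 9.16% of summits and 13.6% of flanks (exact test, adjusted p = 3.6e-14), and CAGGTAG, the site of the early activator Zelda, at 0.337% and 0.738% (adjusted p = 0.005). The N-box CACNAG (10.3% and 13.1%, exact test, adjusted p = 2.2e-06) and CAGCTG (3.93% and 5.31%, adjusted p = 0.00049) were also less frequent at summits. Against dinucleotide shuffles the log2 ratio of CACNAG, CAGCTG and GAGAG turned to 0.08, 1.46 and 0.40, the last 2 past the test. The CAGGTAG call was lost with each replicate left out (exact test, adjusted p = 0.75, 0.23 and 0.14 without replicates 1, 2 and 3, with log2 ratio −0.2 in place of −1.11 without replicate 1). It was also lost with the strongest peaks, farther flanks, shuffles and summits away from promoters. The CAGCTG call was lost without replicate 2 or 3 (exact test, adjusted p = 0.38 and 0.17), and the CACNAG call without replicate 3 (adjusted p = 0.1) and away from promoters (adjusted p = 0.3). CATATG, CAGATG, GGCACGTG, TGGCACGTG and CGTGGGAA, the last a site of Su(H), did not pass the test against these flanks. In other settings, lower shares at summits were called for CAGATG without replicate 1 (exact test, adjusted p = 0.0023) and for CGTGGGAA without replicate 3 (adjusted p = 0.011) and with windows of 100 bp either side (adjusted p = 0.035). CATATG was called more frequent than in shuffles (1.34-fold, exact test, adjusted p = 0.0085). Among all words of 6 bases, pooled with their reverse complements and ranked by the ratio of summit to flank windows, TAGCTA ranked 1, TATCGA 2, CGATAG 3 and ACACTG 6. The words ATATTA, TTATAA, TTTAAA and TATTAA, of A and T alone, ranked 4, 5, 7 and 8, and the last was CTCCTC. CACGTG ranked 1535 and CACGCG 1922, in a ranking that was not corrected for the lower GC content of summits.

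**Figure D3:**
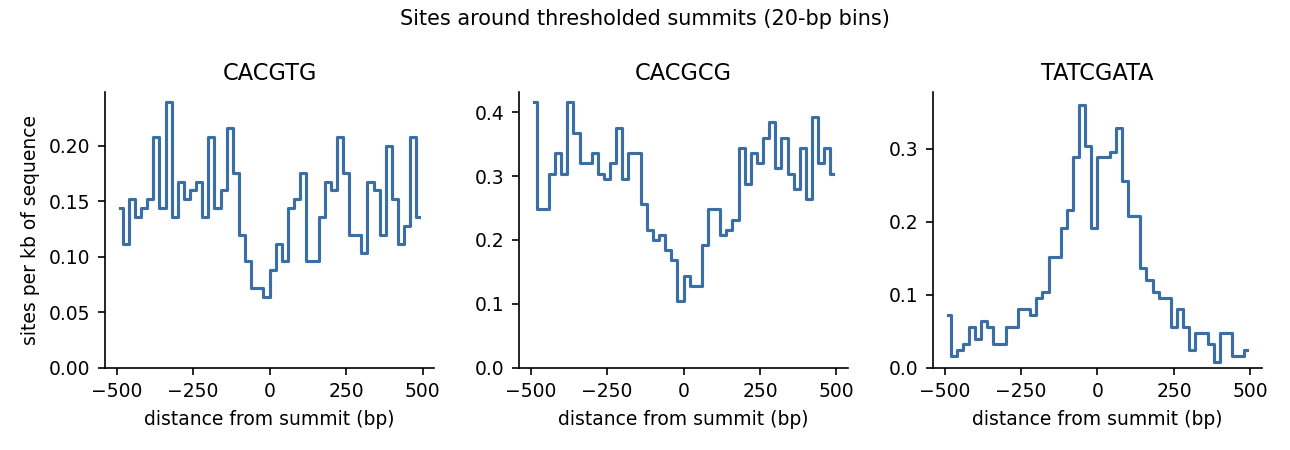
Density of CACGTG, CACGCG and TATCGATA (vertical axes, sites per kb, each on its own scale) by distance from the summit (horizontal axes, bp, bins of 20 bp) over the 6253 thresholded summits. Both E-box forms dip at the summit, and TATCGATA rises there over a region that extends past 100 bp on either side.

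Of 13945 protein-coding genes, 4063 (29.1%) were bound by the nearest-start rule. Ribosomal protein genes were bound most often for their size: 56 of 92 had a peak where 22.8 were expected from the length of sequence around them (2.46-fold, exact stratified test, adjusted p = 1.2e-12). The strongest were at RpS27 (signal 789.97), RpL34b (789.1), RpL7 (777.41) and RpL23A (629.14). This list had been set up as one without expected regulation by Dpn. The other such list, proteasome genes, had 11 of 32 bound against 7.12 expected (1.55-fold, exact test, adjusted p = 0.32), led by Rpn3 (545.38), Rpn6, Rpn11 and Rpn13. It was called where a summit in the gene body or 5 kb around it counted (25 of 32, 1.44-fold, exact test, adjusted p = 0.036).

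Cell cycle genes were bound in 13 of 22 cases against 6.49 expected (2-fold, exact stratified test, adjusted p = 0.04). Their strongest peaks were at CycB, a mitotic cyclin gene (1562.16), Dp, the E2F partner gene (693.99), trbl (489.56) and CycE (443.46). With replicates 1, 2 and 3 left out in turn the fold was 1.82, 1.84 and 1.79 and the call was lost (exact test, adjusted p = 0.24, 0.3 and 0.17). The call was also lost with the 3126 strongest peaks (2.09-fold, exact test, adjusted p = 0.22), with a summit within 1 kb of the start (1.64-fold, adjusted p = 0.099) and with genes of the relaxed pooled list as background (1.45-fold, adjusted p = 0.39). The call was kept with a summit in the gene body or 5 kb around it (1.42-fold, exact test, adjusted p = 0.036), with nearest starts within 10 kb (2.05-fold, adjusted p = 0.035) and without strata (2.03-fold, adjusted p = 0.021). Peaks found in all 3 replicates, a set chosen after seeing the data, gave 1.86-fold (exact test, adjusted p = 0.21). The ribosomal protein list passed in each of these settings, at 1.48-fold to 3.1-fold.

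No list of Notch or neural genes passed the test by the nearest-start rule. The power to find differences of the size seen in these lists was not simulated. Notch pathway components had 11 of 19 bound (1.62-fold, exact stratified test, adjusted p = 0.2), led by the corepressor gene gro (1078.66), numb (992.39), neur (508.37) and mam (287.64). The Hairy/Deadpan family had 7 of 13 bound (1.93-fold, exact test, adjusted p = 0.2), with E(spl)m3-HLH (474.87), cwo (421.68), E(spl)m7-HLH (269.46) and E(spl)mdelta-HLH (202.52) first, and with dpn, her, Hey, E(spl)mbeta-HLH, E(spl)m5-HLH and E(spl)m8-HLH unbound. The E(spl) and Bearded complexes, which are known Notch targets, had 6 of 15 bound (1.44-fold, exact test, adjusted p = 0.5), led by E(spl)malpha-BFM (554.61). Proneural genes and their partners had 2 of 11 bound (0.54-fold, exact test, adjusted p = 0.5), namely da (296.15) and emc (179.62). The 9 unbound members were ac, sc, l(1)sc, ase, ato, amos, cato, tap and HLH54F. Neuroblast factors had 12 of 24 bound (1.22-fold, exact test, adjusted p = 0.5), led by numb, brat (831.11), scrib (470.43) and grh (460.77). Temporal and spatial neural patterning factors had 10 of 25 (0.9-fold, exact test, adjusted p = 0.8), led by chinmo with 10 peaks (1391.79), slp2 (812.05), hth with 10 peaks (470.32) and grh. Neuronal differentiation markers had 4 of 18 (0.53-fold, exact test, adjusted p = 0.3), namely elav (1180.96), Syx1A (398.49), Fas2 (150.85) and fne (136.79). Glial markers had 4 of 10 (1.21-fold, exact test, adjusted p = 0.8), namely moody (1401.82), pnt with 10 peaks (496.02), Gli (266.63) and loco (233.73). Where a gene counted as bound only with a summit within 1 kb of its start, the temporal and spatial factors (4 of 25, 0.37-fold) and the neuronal markers (2 of 18, 0.25-fold) were called less often bound than expected (exact test, adjusted p = 0.037 for both). Where a summit in the gene body or 5 kb around it counted, the E(spl) and Bearded complexes were called more often bound than expected, with 12 of 15 (1.82-fold, exact test, adjusted p = 0.036), as were the proteasome genes, a list without expected regulation by Dpn, at the same adjusted p. Genes of these complexes lie close together, so by this rule the same summit can count for several neighbours. The test treats genes as independent, so its p overstates the evidence for the complexes. By the 1 kb rule the E(spl) and Bearded complexes had 4 of 15 bound (0.96-fold), neuroblast factors 6 of 24 (0.64-fold) and Notch components 12 of 19 (1.85-fold), none past the test. The Hairy/Deadpan family had 4 of 13 bound by the 1 kb rule (1.16-fold). With the gene body or 5 kb around it, 11 of its 13 members were bound (1.57-fold, exact test, adjusted p = 0.077). Several members of this family are neighbours in the E(spl) complex, so the same limit holds for this count.

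The segmentation lists did not pass either. Gap genes had 2 of 11 bound (0.42-fold, exact stratified test, adjusted p = 0.32), namely ems (359.93) and oc (282.82), with hb, Kr, kni, knrl, gt, tll, hkb, cad and btd unbound. Pair-rule genes had 6 of 10 bound (1.41-fold, exact test, adjusted p = 0.5), led by slp2, ftz (243.14), odd (207.38) and hry, the gene of Hairy (198.99), with eve, run, prd and Ten-m unbound. Segment polarity genes had 7 of 12 bound (1.3-fold, exact test, adjusted p = 0.5), led by nkd (626.76), mid (413.29), ptc (408.79) and Wnt4 (321.97). Hox genes had 6 of 8 bound (1.6-fold, exact test, adjusted p = 0.34), led by Antp with 6 peaks (333.57) and Abd-B with 5 (320.8). Sex determination and dosage compensation genes, a process in which dpn is known to act as an autosomal element, had 7 of 16 bound (1.36-fold, exact test, adjusted p = 0.5). These were led by gro, fl(2)d (512.44), Sxl, the master switch of fly sex, with 5 peaks (403.33), and upd1 (318.32). With a summit within 1 kb of the start, gap genes had 0 of 11 bound, pair-rule genes 0 of 10, Hox genes 1 of 8 (0.29-fold) and segment polarity genes 3 of 12 (0.76-fold), none past the test.

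Lists that stand for other tissues of the embryo gave no call. EGFR and dorsal-ventral patterning genes had 11 of 15 bound (1.8-fold, exact stratified test, adjusted p = 0.095), led by aos (971.13), spi (880.13), pnt and dpp (490.15). Endoderm and gut genes had 8 of 10 (1.97-fold, exact test, adjusted p = 0.095), led by Fas3 (453.9), tin (430.53), Hnf4 (411.78) and fkh (315.38). Mesoderm and muscle genes had 9 of 17 (1.36-fold, exact test, adjusted p = 0.5), led by zfh1 (839.87), Mef2 (683.3), tin and htl (381.99). Tracheal genes had 6 of 10 (1.39-fold, exact test, adjusted p = 0.5), led by vvl (363.84), trh (301.77), ttk (251.76) and bnl (201.82). Hemocyte and fat body genes had 4 of 12 (0.93-fold, exact test, adjusted p = 1), led by ush with 12 peaks (443.5) and crq (425.68). Epidermal genes had 5 of 11 (1.1-fold, exact test, adjusted p = 0.8), led by grh and ovo (324.83). By the 1 kb rule the ratio was 0.95 for the EGFR list, 1.05 for endoderm, 0.73 for mesoderm, 0.55 for trachea, 0.42 for hemocytes and fat body and 0.47 for epidermis, none past the test. Without strata for neighbourhood length, 6 lists passed, with the Notch, Hox, endoderm and EGFR lists among them.

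**Figure D4:**
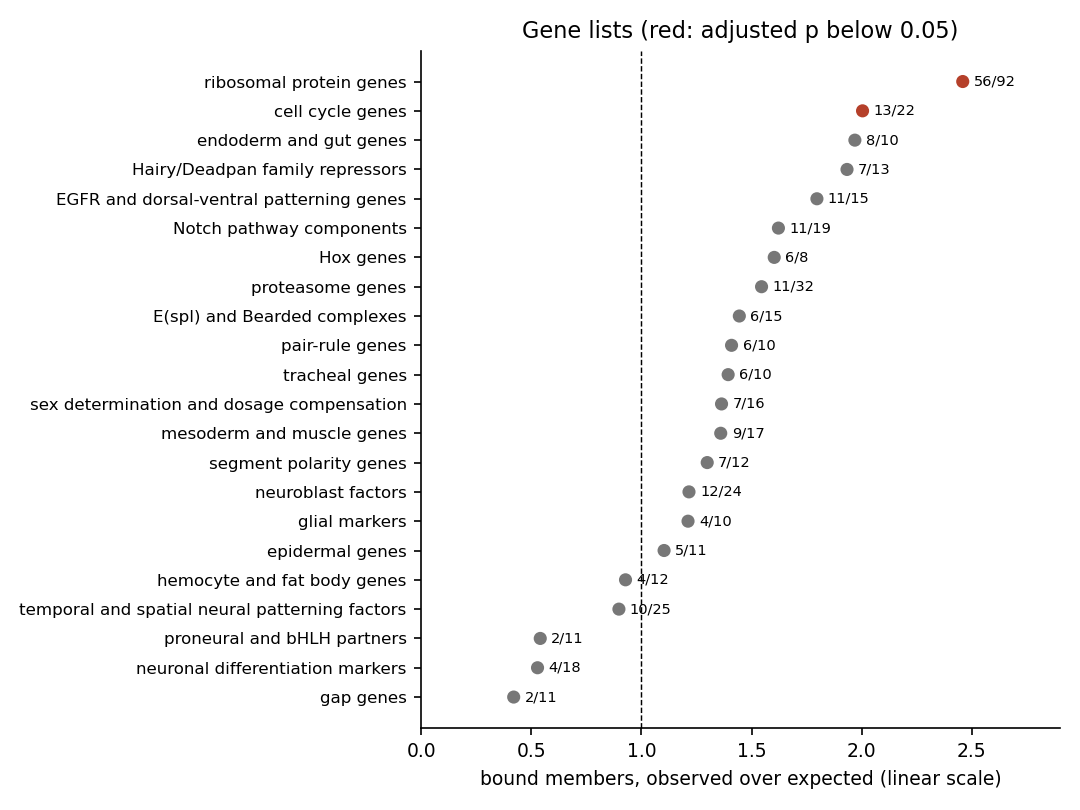
Bound members over the number expected (horizontal axis, ratio on a linear scale) for the 22 gene lists (vertical axis), with bound and total members beside each point and the expectation at the dashed line. The ribosomal protein list (56 of 92, 2.46-fold) and the cell cycle list (13 of 22, 2-fold), in red, passed an adjusted p of 0.05.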

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

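The alternative that kept the peaks found in all 3 replicates was chosen after seeing the data, and the others were planned. The direction and call of the promoter, intron and intergenic shares held under every alternative run, with the promoter share between 2.62-fold and 4.32-fold, as did the lack of a relation between signal and Dpn sites. The number of peaks fell to 3126 when those of highest signal were kept, by construction. The mean replicate share was 66.1% with a 50% reciprocal overlap, 70.6% with summits within 100 bp and 61.3% with all peaks of each list, and between 72.9% and 82.1% with 1 replicate left out. Support in all replicates was 60.4% with summits within 100 bp, 93.2% with 2 times as many peaks of each replicate, and between 70.8% and 80.6% with 1 replicate left out, which asks for 2 replicates in place of 3.

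The lower share of CACGTG at summits lost its call with the 3126 strongest peaks (log2 ratio −0.71), windows of 100 bp either side (−0.37), flanks 1000 bp away (−0.43), dinucleotide shuffles (−0.48) and GC-matched low-ranked peaks (−0.29), and lay between −1.01 and −0.61 with 1 replicate left out, where leaving out replicate 3 ended the call. CACGCG lost it with shuffles (−0.42) and GC-matched peaks (−0.0192), and CACGNG turned to 0.0271 with GC-matched peaks. Other called words whose log2 ratio turned positive were CACNAG (0.0782 with shuffles, 0.25 with GC-matched peaks), CAGCTG (1.46 and 0.61), GAGAG (0.40 and 0.0297) and, with GC-matched peaks, CAGGTAG (1.18). The opposite direction passed the test for CAGCTG in both, GAGAG with shuffles and CACNAG with GC-matched peaks (exact test, adjusted p = 0.013). Among words without a call, CAGATG turned to 0.231 and 0.261, and GGCACGTG to 1.08 without replicate 3. These control sequences share the base composition of the summits by construction. The number of gene lists that passed was 1 with the 3126 strongest peaks, 1 with any 1 replicate left out, 1 with genes of the pooled relaxed list as background, 1 with peaks found in all 3 replicates, 4 with summits in the gene body or 5 kb around it, and 6 with no strata, and the cause was not tested. Ribosomal protein genes passed in each of them. Read depth was not given in the sources used here, so how far it limits the weakest peaks is open.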

Other observations

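The share of CACGTG or CACGCG at promoter summits, its comparison with flanks, the relation of these sites to signal and the shares of TATCGATA over flanks, also with 1 replicate left out, were planned, and the other tests in this part, as well as the use of the last to weigh a mislabelled library, were chosen after the results had been seen.

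Promoter summits sat upstream of the start of transcription. Of 3095 promoter summits with a protein-coding start within 500 bp, 85.7% lay upstream of it, at a median of −95 bp (quartiles −178 and −38 bp, negative values upstream). Promoters shared by genes that face away from each other were bound more often than others. Among 13126 regions within 500 bp of protein-coding starts, 1017 of 1859 that held start sites facing away from each other no more than 500 bp apart had a summit (54.7%), where 767 were expected from the width of the regions (1.33-fold, exact stratified test, p = 4.7e-62). Of the other 11267 regions, 15.7% had one.

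Some words, among them words known from chromatin boundary and promoter proteins, were more frequent at summits than beside them. They were picked from words frequent in the same windows, so no p is given for the excess. The intervals below take no account of that choice and are not a test of the excess. AGATGGCGC or AGGTGGCGC, forms of the site of the boundary protein CTCF, lay at 1.62% of summits and 0.241% of flanks (6.73-fold), both at promoters (5.33-fold) and away from them (6.11-fold). At promoters with a summit the share was 1.36%, against 0.127% at the same distances from the start in 10264 promoters without one (10.7-fold, 95% interval 5.76 to 19.9). GGTCACAC, part of the site of the promoter protein M1BP, was at 2.44% of promoter summits and 0.401% of their flanks (6.08-fold), but only 1.76-fold (1.34 to 2.3) more frequent than at promoters without a summit. CACTGAGA, to which no protein was assigned here, was at 1.74% of the summits outside promoters and 0.368% of their flanks (4.73-fold). At promoters CACTGAGA was 1.9-fold over flanks, 3.8-fold over shuffles and 1.81-fold over promoters without a summit.

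TATCGATA, GGTCACAC and GC content varied with the signal of the peak. TATCGATA was at 1.04% of summits in the strongest quintile and 3.28% in the weakest (Spearman rho across peaks −0.057, permutation p = 1e-05, the smallest that can be given, adjusted p = 3e-05 over 6 tests). The GC content of the windows was 32.5% in the strongest quintile and 36.0% in the weakest (rho −0.14, permutation test, adjusted p = 3e-05). GGTCACAC had a rho of −0.049 (permutation test, adjusted p = 0.00024). The CTCF forms (rho 0.019, permutation test, adjusted p = 0.19), CACTGAGA (rho −0.012, adjusted p = 0.34) and the Dpn sites (rho −0.014, adjusted p = 0.34) showed no called trend. The promoter share was 64.0% in the strongest quintile and 46.6% in the weakest.

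The first pattern is the placement of summits at promoters. A CACGTG or CACGCG site at most promoter summits is excluded by the upper bound of 3.12% on the share with either within 50 bp. Such a site did not mark the bound promoters either, at 0.864-fold (95% interval 0.679 to 1.1, exact Fisher test, p = 0.25) the share of promoters without a summit, though the GC content of the windows was 36.0% and 40.3%. Signal at open promoters without a Dpn site remains a candidate explanation. Promoter summits carried either site at 0.512-fold the share of their flanks (exact McNemar test, p = 3e-07). Against shuffles the share was also lower, at 0.656-fold (82 against 125 of 3250, exact McNemar test, adjusted p = 0.0034). The share below that of flanks does not weigh for this explanation, since summits are lower in GC and flanks of promoter summits were not matched on it. The share below that of shuffles does not weigh for it either, since flanks of promoter summits were not set against their own shuffles. Recruitment of Dpn by other proteins also predicts no excess of Dpn sites. Neither chromatin opening nor a control precipitation was analysed here, so no biological explanation other than a Dpn site was tested.

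The second pattern is the lower share of Dpn sites at summits than in flanks, 0.442-fold for either site. GC content may account for it, since the log2 ratio was −0.203 (95% interval −0.573 to 0.167, exact Fisher test, p = 0.31) over flanks of the same GC content, in 3744 windows of 39.0% GC on average. Set against 10 dinucleotide shuffles of each window, the log2 ratio was −0.671 at summits and −0.281 at flanks, a difference of −0.39 (bootstrap 95% interval −0.715 to −0.0881) that shuffling did not remove. The interval of the GC-matched comparison includes that difference as well as 0, so whether base composition is the whole cause stays open. A log2 ratio of 0.0359 (95% interval −0.324 to 0.396) over low-ranked peaks matched on GC decides nothing, since those are peaks of the same call, and the other tests were written after it and a 0.732-fold share against shuffles (exact McNemar test, adjusted p = 0.009) had been seen.

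The third pattern is TATCGATA at promoter summits, 18.4-fold over flanks. Base composition is excluded by a 49.3-fold excess over shuffles of the same windows (148 against 3 of 3250). A word shared by all promoters accounts for part, with 1.94% at the same distances in promoters without a summit, and not for the whole, with 4.78% at those with one (2.47-fold, 95% interval 2.0 to 3.04, at 40.3% and 36.0% GC). A single mislabelled library is argued against by the excess over flanks at all summits, 8.56-fold with all replicates and 5.0-fold, 9.4-fold and 8.15-fold without replicates 1, 2 and 3, a test not run at promoter summits alone. An antibody or tag that favours accessible promoters in all 3 libraries, or a label error of the whole experiment by which every value given for Dpn would belong to another protein, stays open, as does the untested hypothesis that the tagged protein lies near Dref, M1BP or CTCF, which the overlap with peaks of these proteins in embryos of this age would test.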
